A study of Drosophila melanogaster with 27 samples.

How the data were processed

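Gene expression in Drosophila eye imaginal discs was read from 27 glass arrays printed with PCR products, each carrying 2 RNAs in the dyes Cy5 and Cy3. Per the labels, the test RNA came from L3 larvae, from w1118 disc fragments behind the morphogenetic furrow or from whole discs of a mutant. It was amplified by 2 rounds of T7 transcription. The other channel held a common reference of w1118 whole eye-antennal discs, amplified by 1 round. No control sample was hybridised against this reference, so a ratio tested against 0 treats the reference as 1 control sample, leaves out its own spread and holds any effect of the extra round. Differences between 2 test groups are free of both limits.

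Per the file headers, the scanner files give the pixel intensity of each of 17664 spots per array in both channels, with the local background and its SD. The deposited scanner files also hold the percent of saturated pixels of each spot and a score per spot that marks spots as bad, absent or not found. The deposited value table holds the log2 ratio of reference over test made by the authors, shifted by a constant per array, and was used only as an alternative. Spots with a score of -75 or lower were left out, and background was subtracted with the normexp method of limma and an offset of 50. Log ratios were normalised within each array by a global loess curve in which control spots had no weight. Every array was then turned to test over reference by the dye stated in its labels, and spots of the same probe were averaged. The header of roDom homozygote replicate 2 names the dyes in the other order than its labels. Turned by the labels, its ratios correlated with those of replicate 1 at r = 0.448 and of replicate 3 at r = 0.279 across probes, and turned by the header both would be negative.

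Of 16880 probes with values, 15501 were named through the RefSeq gene table of genome assembly release 6: 12714 by locus tag, 34 by symbol and 2753 by an older synonym. The 1379 unmatched probes stayed in the tests without a name. The named probes covered 11510 genes, and a gene with several probes was represented by its brightest probe. Genome positions in this table served only to find the neighbours of a gene.

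Arrays were grouped by their titles into 9 conditions of 2 to 4 arrays. The labels of 2 arrays conflict: replicates 2 and 3 of the E(roDom)2033 homozygotes are heterozygous in their characteristics, and the titles were used. The source name of 1 roDom heterozygote array gives no zygosity, and its title was used too. All 27 arrays entered 1 limma fit with 9 group means and a dye term per probe, because the dyes were not balanced within groups. Moderated two-sided tests were adjusted by Benjamini-Hochberg within each of 13 comparisons over 16490 probes with at least 2 measured arrays in each group. A probe was called changed at an adjusted p under 0.05. These p-values measure the spread between the arrays at hand, and the number of arrays limits the precision. A value is given as the fitted log2 change ± its standard error.

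Before the data were examined, 20 gene lists were fixed: photoreceptor and neuronal differentiation, morphogenetic furrow and proneural, Notch targets of the E(spl) and Bearded complexes, EGFR pathway, Hedgehog pathway, retinal determination and anterior progenitor, DNA replication, mitosis, antennal disc, glia, hemocyte, fat body, muscle, phototransduction, cell death and JNK, antimicrobial peptides, heat shock, ecdysone response, sex-linked dosage and sex, and cytoplasmic ribosomal proteins. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the 20 lists of a comparison. Of 220 such tests 59 passed. With an estimated correlation 2 passed, the EGFR pathway in ato1 and photoreceptor differentiation in posterior fragments minus stop-furrow discs. With fry, which asks whether the genes of a list move on balance in 1 direction, 50 passed.

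The rule for named genes was also fixed before the data were examined. The mutated genes ro, ato and hh come first. Posterior fragments against the reference and both group differences name the 10 highest and 10 lowest changes past the threshold, and other comparisons the 3 highest and 3 lowest. Such genes need a symbol other than a CG number and, against the reference, the same sign in every array of the group. Their agreement in sign is therefore fixed by the rule. For lists the rule was to name up to 4 members with the largest change, and every member where a count is 5 or fewer, and the text names part of these.

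Alternatives were a fit without the dye term, no background subtraction, print-tip loess, scale normalization between arrays, a filter on dim probes, a stricter score limit, array series as a block, the 7th series alone, the deposited value table, a fit on the groups compared, a 2-fold limit, the other reading of the conflicting labels, and leaving out arrays. Chosen after the data were seen were the day of scanning as a fixed or random block, a run without 3 arrays whose muscle list median was above 0.3, and each condition against the mean of the others. The headers put the arrays into 9 scanning days. Posterior replicate 1, roDom homozygote replicates 1 and 2 and hh1 replicate 1 were each alone on a day. Posterior replicates 2 to 4 shared theirs only with ato1 replicate 1. A fixed block ties such arrays to the other groups weakly or not at all, so calls lost under it need not be day effects. Data were simulated with 100 probes shifted by each of 2 sizes and with noise independent between arrays. The fit recovered 97% of changes of 1 log2 unit in posterior fragments and 72% of changes of 0.5. For roDom homozygotes minus heterozygotes these shares were 66% and 20%. Of the calls on simulated data, 4.27% to 7.53% fell on unchanged probes. The simulations held no effect of scanning day, whereas real arrays of 1 day were correlated (0.262), so these shares may be too favourable. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with matplotlib 3.10.9.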

Results

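The 27 arrays measured RNA levels in eye imaginal discs for 16880 probes, each as the log2 ratio of a test RNA over the w1118 reference. The 9 conditions were w1118 posterior fragments (4 arrays), roDom homozygotes (3) and heterozygotes (2), E(roDom)2033 homozygotes (3) and heterozygotes (2), ato1 (3), hh1 (4), roX63 (3) and Su(roDom)519 (3). The morphogenetic furrow is the front behind which retinal cells differentiate, and R8 is the founder photoreceptor of each facet. Per the series description the furrow stops in ato1, hh1, roDom and E(roDom)2033 discs, and roX63 and Su(roDom)519 discs form extra R8 cells. The 13 arrays of ato1, hh1 and the homozygotes of roDom and E(roDom)2033 are called stop-furrow discs, and the 6 arrays of roX63 and Su(roDom)519 extra-R8 discs. From 47.2% (posterior fragments, replicate 1) to 91.8% (Su(roDom)519, replicate 2) of probes were detected in at least 1 channel. The median net test signal ran from 28 to 367 intensity units, and the number of arrays limits the precision of every value. Changes against the reference can be shared between mutant groups, so the number against the mean of the other conditions stands beside each.

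Posterior fragments against the reference address which transcripts set the differentiating side of the furrow apart. The fragments lack the antennal disc and the anterior eye disc, which the reference holds. A change can therefore come from the tissue left out as well as from differentiation. The fragments held more RNA of chp, which encodes the photoreceptor surface protein chaoptin, with a log2 change of 1.46 ± 0.24 (SE, n = 4 arrays, adjusted p = 0.00098). The sodium pump gene nrv3 of neurons rose by 1.42 ± 0.18 (adjusted p = 6.6e-05), with another probe at 0.02. The Runx transcription factor gene run rose by 1.79 ± 0.18 (adjusted p = 4.1e-06). So did ru, a rhomboid-family protease of EGFR signalling, by 1.54 ± 0.23 (adjusted p = 0.00034). The other named genes that rose were santa-maria, a scavenger receptor of carotenoid uptake (1.80 ± 0.18), mfas, a fasciclin (1.70 ± 0.24, other probes from 0.14 to 1.83), and the sterol-binding Npc2a (1.56 ± 0.23). Of the rest, the piRNA factor krimp (1.48 ± 0.28), the GABA transaminase Gabat (1.41 ± 0.18) and the odorant-binding Obp44a (1.93 ± 0.48) rose. The peptidase gene Ance (-4.68 ± 0.28, adjusted p = 4.8e-09), the dorsal eye gene mirr of the Iroquois family (-2.33 ± 0.25) and the Notch ligand gene Ser (-2.22 ± 0.32) fell. The Hox genes Dfd (-2.31 ± 0.21) and lab (-1.88 ± 0.23) fell as well. Also lower were bnb, a glial gene (-3.57 ± 0.25), Obp99a (-2.96 ± 0.41), and the transcription factor genes opa (-1.93 ± 0.21), ab (-1.81 ± 0.20) and D (-1.80 ± 0.25). By the rule for naming them, each of the 20 genes had the same sign in 4 of 4 arrays. Dfd was detected above background on 2 of them, so the size of its fall rests partly on signal near background. In limma 752 probes changed, 438 higher and 314 lower (1420 against the mean of the other conditions). Without replicate 4 this number was 279 and without replicate 3 it was 472. Obp44a lost its call without replicate 1 (1.39, adjusted p = 0.17) or 4 (1.79, adjusted p = 0.18), as krimp did without replicate 4 (1.20, adjusted p = 0.086). Scanning day as a fixed block left 474 probes, 138 of them among the 752. Under it ru (1.16 ± 0.34), chp (0.96 ± 0.58) and D (-1.01 ± 0.33) had smaller changes with wider standard errors and lost their calls. Obp44a (1.66 ± 0.91), krimp (1.82 ± 0.67), Obp99a (-2.85 ± 0.91) and Dfd (-1.93 ± 0.50) lost theirs mainly through wider standard errors. With it as a random block 20 of the 20 genes kept their calls.

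**Figure D1:**
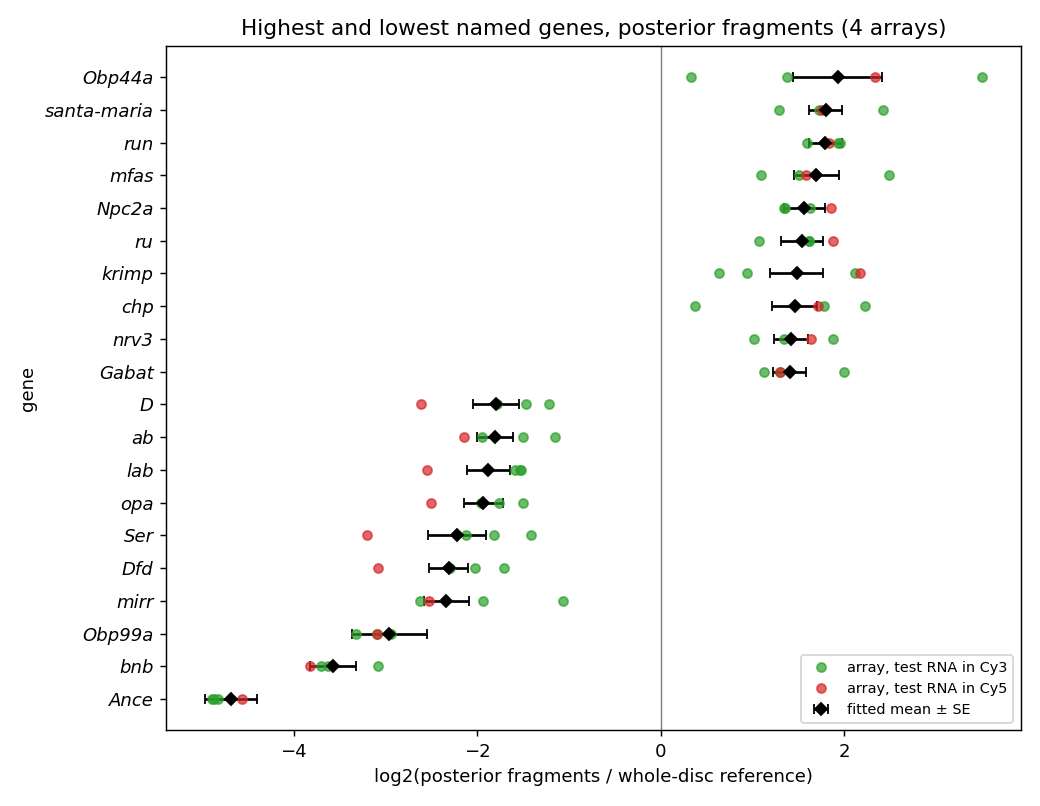
Log2 ratio of posterior fragments over the reference (horizontal axis) for the 20 named genes. Points are the 4 arrays, coloured by the dye of the test RNA, and markers with bars are the fitted mean and its standard error, from 1.93 for Obp44a to -4.68 for Ance.

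Among the fixed gene lists in posterior fragments, photoreceptor and neuronal differentiation rose as a set (camera, adjusted p = 0.012, and adjusted p = 0.43 with an estimated correlation). Of its 29 measured genes 3 rose (chp, nrv3 and scrt, a neuronal zinc finger gene, 1.04 ± 0.23), 1 fell (ttk, a repressor of neuronal fate, -1.38 ± 0.26, other probes from -0.57 to 0.06) and 25 did not pass. Adjusted over the list alone, 6 rose and 1 fell. Retinal determination and anterior progenitor genes fell as a set (adjusted p = 0.012, and adjusted p = 0.43 with an estimated correlation). Of 20 genes mirr, the Pax6 gene toy (-1.74 ± 0.34) and the Notch modifier fng (-0.87 ± 0.15) fell and 17 did not pass, or 7 fell and 1 rose adjusted over the list alone. The ecdysone response list also fell (adjusted p = 0.034, and adjusted p = 0.71 with an estimated correlation), with 3 of 15 genes lower. These were br (-0.94 ± 0.22, other probes from -0.53 to 0.07), Hr3 (-0.81 ± 0.23, another probe at 0.11) and Ldh (-0.23 ± 0.07), also 3 adjusted over the list alone. Mitosis genes were lower as a set (adjusted p = 0.034, and adjusted p = 0.84 with an estimated correlation), with no single member of 24 past the threshold. Without replicate 1 the mitosis list did not pass (adjusted p = 0.90), nor did the photoreceptor list without replicate 4 (adjusted p = 0.092) or the ecdysone list without replicate 2, 3 or 4. The other 16 lists did not pass, with adjusted p from 0.097 for the furrow, Notch and DNA replication lists to 0.99 for the antennal list. Without replicate 2 scrt reached 0.88 (adjusted p = 0.076), without replicate 3 0.95 (0.063) and without replicate 4 1.01 (0.095). The value of toy without replicate 4 was -1.57 (0.066). The calls of br, Hr3 and Ldh were each lost without replicate 4 (-0.95, -0.63 and -0.22), replicate 3 (-0.86, -0.75 and -0.22) or replicate 2 (-0.91, -0.71 and -0.24). That of Ldh was also lost without replicate 1 (-0.24). With scanning day as a fixed block the calls of chp (0.96), ttk (-0.59), scrt (1.48), br (-0.49), Hr3 (-1.24) and Ldh (-0.17) were lost, and as a random block those of br (-0.81), Hr3 (-0.73) and Ldh (-0.22).

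Posterior fragments minus stop-furrow discs compare differentiating tissue with discs in which differentiation halts, and the reference cancels. The mutant discs hold the antennal disc and the anterior eye disc, which the fragments lack. Differences in either direction can thus come from the dissection as well as from differentiation. Among genes of photoreceptor and neuronal differentiation, chp was higher in the fragments by 3.19 ± 0.28 (n = 4 against 13 arrays, adjusted p = 1e-07) and scrt by 2.54 ± 0.26. The neuronal ankyrin gene Ank2 was higher by 3.07 ± 0.24, with its other probes from -0.04 to 0.18. So were ru (3.34 ± 0.26), the bHLH Notch target E(spl)mgamma-HLH (3.38 ± 0.25), the adhesion gene Nrt (3.25 ± 0.25, other probes from 0.17 to 0.20) and run (2.61 ± 0.20). Further up were the tachykinin receptor gene TkR86C (2.63 ± 0.28), the tetraspanin gene Tsp42El (2.56 ± 0.24) and Xport-A, a chaperone of rhodopsin and TRP channels (2.69 ± 0.11, adjusted p = 4.3e-12). The stop-furrow genotypes were not alike in part of these genes. The difference of ato1 minus hh1 was -3.15 ± 0.37 for chp, -2.95 ± 0.35 for ru, -2.61 ± 0.34 for Nrt and -2.53 ± 0.31 for Ank2. A difference from the stop-furrow mean thus need not hold against each genotype alone. Lower in the fragments were Ance (-5.45 ± 0.32, adjusted p = 8.9e-10), Obp99a (-4.53 ± 0.46), Vajk2 (-3.31 ± 0.40, another probe at -1.07) and Vajk3 (-2.86 ± 0.21) of the Vajk family, and bnb (-2.52 ± 0.28). The transcription factor genes opa (-2.30 ± 0.24), D (-2.30 ± 0.28), toy (-2.26 ± 0.38) and Dfd (-2.15 ± 0.24) and the ligand gene Ser (-2.28 ± 0.36) were lower too. The size for Dfd rests partly on signal near background in the fragments. The mutated gene hh, which encodes the Hedgehog ligand, was higher by 1.61 ± 0.19 (adjusted p = 6.7e-06), while ro (0.13, adjusted p = 0.67) and ato (-0.01, adjusted p = 0.99) did not pass. In limma 1343 probes differed, 839 higher and 504 lower, and 788 without posterior replicate 4. With scanning day as a fixed block 538 passed, 296 of them shared, and bnb (-1.09 ± 0.36), D (-1.10 ± 0.38) and Dfd (-1.69 ± 0.57) lost their calls. As a random block it left 891, of which 878 were shared, and kept the calls of 20 of the 20 genes with the largest changes.

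Photoreceptor differentiation was the list with the lowest p between fragments and stop-furrow discs: 10 of 29 genes were higher and 19 did not pass. Among the 10 were chp, scrt, nrv3 (2.49 ± 0.21, with another probe at -0.04) and the receptor kinase gene sev (1.97 ± 0.23). The set test gave an adjusted p = 2.2e-06, and adjusted p = 0.038 with an estimated correlation. Adjusted over the list alone, 12 genes passed. In the EGFR pathway list ru, rho (2.52 ± 0.24), aos (1.94 ± 0.16) and aop (1.5 ± 0.29) were the highest. Of 17 genes 6 passed, or 7 adjusted over the list alone (adjusted p = 5.6e-06, and adjusted p = 0.089 with an estimated correlation). Of 15 Notch targets E(spl)mgamma-HLH, E(spl)mdelta-HLH (2.17 ± 0.19) and E(spl)m2-BFM (0.84 ± 0.16) were higher. That was 3 genes, or 4 adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.56 with an estimated correlation). DNA replication genes were lower as a set (adjusted p = 0.0016, and adjusted p = 0.56 with an estimated correlation), and not without posterior replicate 1 (-0.13, adjusted p = 0.074). In that array, which detected 47.2% of probes, the list's median was -0.44, against -0.04 to 0.00 in the other 3. The ribonucleotide reductase gene RnrS (-0.71 ± 0.17) and the origin genes Orc2 (-0.68 ± 0.16, other probes from -0.50 to 0.00) and Orc1 (-0.26 ± 0.07) of 26 passed, or 4 adjusted over the list alone. In the hemocyte list lz, a Runx gene that photoreceptor precursors also use (1.72 ± 0.23), SPARC (1.46 ± 0.33) and Ppn (0.76 ± 0.17) of 10 were higher. Adjusted over the list alone there were also 3 (adjusted p = 0.0083, and adjusted p = 0.35 with an estimated correlation). Ribosomal protein genes were lower as a set, with 5 of 90 past the threshold and 1 adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.90 with an estimated correlation). The Notch list did not pass without posterior replicate 3 (adjusted p = 0.27), the hemocyte list without posterior replicate 4 (adjusted p = 0.15) and the ribosomal list without posterior replicate 2 (adjusted p = 0.47). Without posterior replicate 1, RnrS reached -0.50 (adjusted p = 0.080), Orc2 -0.46 (0.052) and Orc1 -0.20 (0.17). Orc1 also lost its call without posterior replicates 2 (-0.27) or 3 (-0.27) or E(roDom)2033 homozygote replicate 1 (-0.22). Without posterior replicate 4, SPARC reached 1.20 (0.077) and Ppn 0.60 (0.081). Blocking scanning day as fixed ended the calls of sev (1.62), hh (1.33), lz (1.70), SPARC (1.92), Ppn (0.67), RnrS (-1.02), Orc2 (-0.80) and Orc1 (-0.41), while as a random block it kept all 8.

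Extra-R8 minus stop-furrow discs compare genotypes described as forming extra R8 cells with genotypes in which the furrow stops. R8 cells were not counted, and arrays rather than genotypes are the units of the tests. Setting E(roDom)2033 homozygotes and hh1 against the rest of these genotypes called 2020 probes, against 1239 for this grouping. Of 15 Notch target genes 5 were higher in extra-R8 discs, among them E(spl)mgamma-HLH by 3.78 ± 0.22 (n = 6 against 13 arrays, adjusted p = 2.1e-09) and E(spl)m4-BFM by 2.14 ± 0.39 (adjusted p = 0.0021). The difference of E(spl)mdelta-HLH was 2.01 ± 0.17 (adjusted p = 4.5e-07) and that of Brd 1.67 ± 0.33 (adjusted p = 0.0040). E(spl)mgamma-HLH lay between 0.49 and 1.69 in the 6 extra-R8 arrays and between -4.76 and -0.82 in the 13 others. Also higher were the tetraspanin gene lbm (2.33 ± 0.21), the integrin gene if (2.16 ± 0.22), Npc2a (2.05 ± 0.22), Lfg (2.03 ± 0.17) and Nrt (1.84 ± 0.22, other probes from 0.17 to 0.27). The same held for phyl, an adaptor for the breakdown of the repressor Ttk (1.65 ± 0.30). Lower were Vajk2 (-2.39 ± 0.35, another probe at -0.85) and Vajk3 (-2.26 ± 0.19), the serpin gene Spn43Aa (-1.83 ± 0.31), the actin nucleation gene Arpc1 (-1.59 ± 0.25), and hui (-1.43 ± 0.30). The Sox gene D (-1.29 ± 0.25), the transporter gene Oatp74D (-1.26 ± 0.25), Dfd (-1.21 ± 0.21), the chitinase gene Cht5 (-1.12 ± 0.24) and the protease gene spirit (-1.11 ± 0.34, adjusted p = 0.050) were lower as well. The proneural gene ato was higher by 0.41 ± 0.10 (adjusted p = 0.013), and ro (0.18, adjusted p = 0.39) and hh (-0.00, adjusted p = 1) did not pass. In limma 1239 probes differed, 677 higher and 562 lower. Without roX63 replicate 3 the number was 734, and ato lost its call without Su(roDom)519 replicate 1 (0.37, adjusted p = 0.053). The call of spirit was lost in 16 of 19 runs that each left out 1 array, with values from -1.22 (without roX63 replicate 3) to -0.94 (without hh1 replicate 4). A fixed block for scanning day left 357 probes, 99 of them shared. Under it ato (0.58), Spn43Aa (-0.56 ± 0.36), hui (-0.99 ± 0.28), D (-0.63 ± 0.33), Oatp74D (-0.64 ± 0.43), Dfd (-1.25 ± 0.49), Cht5 (-0.34 ± 0.34) and spirit (-0.41 ± 0.58) lost their calls. As a random block it left 472, of which 471 were shared, and ended the calls of spirit (-0.96) and ato (0.43).

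**Figure D2:**
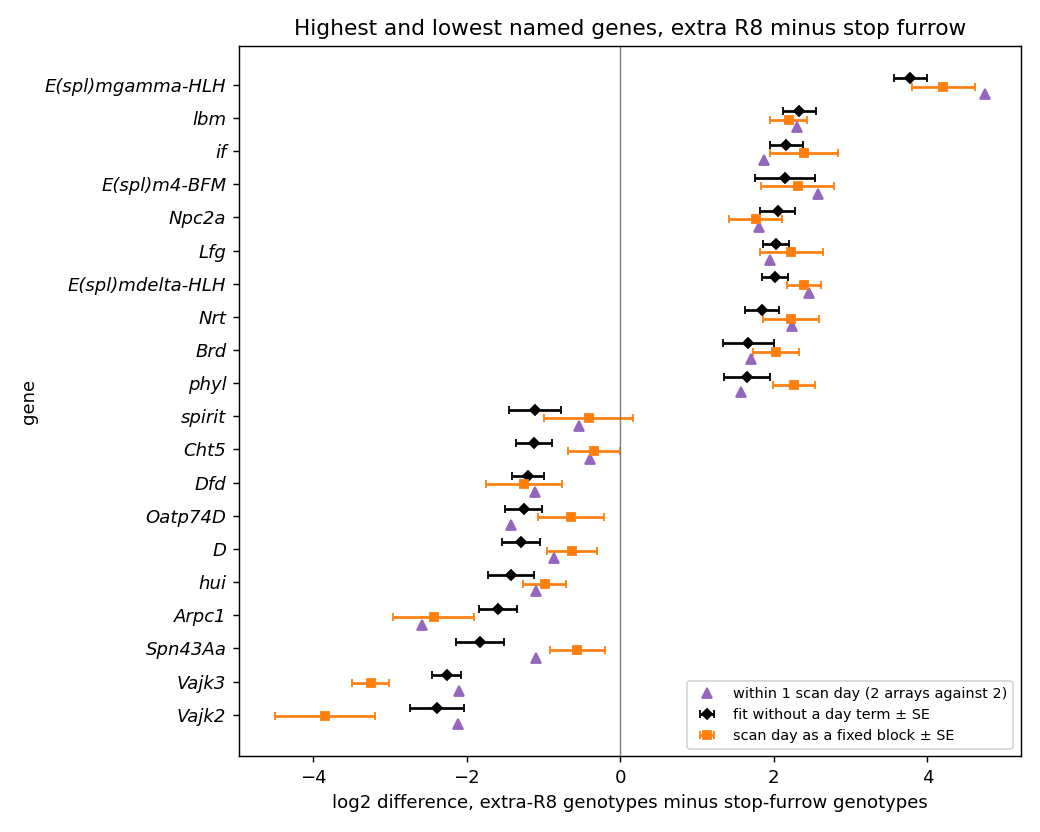
Log2 difference of extra-R8 minus stop-furrow discs (horizontal axis) for the 20 named genes. Markers show the fit without a day term (with standard error), the fit with scanning day as a fixed block (with standard error) and the difference within 1 scanning day from 2 arrays against 2, which are also in the fit that chose the genes. The difference of E(spl)mgamma-HLH was 3.78 without a day term and 4.21 with it, and that of Cht5 went from -1.12 to -0.34.

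The list of Notch targets passed, with 10 of its genes not past the threshold and 6 higher adjusted over the list alone (adjusted p = 2.4e-05, and adjusted p = 0.23 with an estimated correlation). The photoreceptor list was higher too, led by phyl, lz (1.27 ± 0.21), scrt (1.22 ± 0.23) and nrv3 (1.12 ± 0.18, with another probe at -0.03). Of 29 genes 6 passed, or 7 adjusted over the list alone (adjusted p = 0.0043, and adjusted p = 0.23 with an estimated correlation). Outside these 2 lists, stg and dap, regulators of cell division in the furrow list, were higher by 1.32 ± 0.20 and 1.21 ± 0.22, though that list did not pass (adjusted p = 0.25). The cell death list did not pass either (adjusted p = 0.30). In it rpr (-0.84 ± 0.11) and the caspase gene Dcp-1 (-0.73 ± 0.10) were lower and the ligand gene egr higher (0.67 ± 0.15). Of 10 heat shock genes Hsp67Bc was higher (1.06 ± 0.20) and Hsp23 (-1.02 ± 0.20), Hsp27 (-0.71 ± 0.20) and Hsc70-4 (-0.27 ± 0.07) were lower, and the list did not pass (adjusted p = 0.81). The remaining lists had adjusted p from 0.075 (EGFR and hemocyte) to 0.92 (antimicrobial peptides). With scanning day as a fixed block lz (1.59), scrt (1.29), stg (1.18), dap (1.11), rpr (-0.87), Dcp-1 (-0.51) and egr (0.61) no longer passed. Nor did Hsp67Bc (1.41), Hsp23 (-0.78) and Hsc70-4 (-0.14), and Hsp27 turned to 0.09. Among these 11 genes a random block ended the calls of Hsp27 (-0.56) and Hsc70-4 (-0.23). Leaving out roX63 replicate 3 ended the calls of Hsp27 (-0.59) and Hsc70-4 (-0.22), and so did leaving out Su(roDom)519 replicate 1 (-0.72 and -0.22). Hsp27 also lost its call without roDom homozygote replicates 1 (-0.69) or 2 (-0.69), hh1 replicate 4 (-0.64), or Su(roDom)519 replicates 2 (-0.67) or 3 (-0.74).

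The 438 probes higher in posterior fragments were tested as a set in extra-R8 minus stop-furrow discs. Their median difference was 0.09, against -0.01 for the other probes, and 66.4% were above 0 (camera, adjusted p = 2.3e-07, and adjusted p = 0.045 with an estimated correlation). Of them 78 were called higher and 15 lower. The 314 probes lower in the fragments had a median of -0.06, with 17 called higher and 56 lower (p = 0.0025, and p = 0.23 with an estimated correlation). This lower set did not pass with the deposited values (-0.00106), without roX63 (-0.0137) or without roDom homozygotes (-0.0361). Across 16490 probes, which are not independent replicates, Pearson's r was 0.190 and Spearman's rho 0.044. In 20 simulations without any change or effect of scanning day r was -0.045 on average and ran from -0.075 to -0.005. With scanning day as a fixed block in both steps the sets, called anew, had medians of -0.28 and 0.22. Those called without the block had 0.10 and 0.04.

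In ato1 discs, mutant for the proneural gene ato, Notch and EGFR signalling genes were lower than in the reference. E(spl)mgamma-HLH fell by 4.46 ± 0.25 (n = 3 arrays, adjusted p = 2e-10), and ru (-2.97 ± 0.26), rho (-2.40 ± 0.24), chp (-3.37 ± 0.28) and scrt (-2.60 ± 0.26) fell too. Also lower were the RNA-binding Hrb87F (-3.75 ± 0.16) and the receptor gene Ir76a (-3.70 ± 0.17). Higher were Vajk3 (4.05 ± 0.22), Vajk2 (3.83 ± 0.40, another probe at 0.91) and Hsc70-2 (2.57 ± 0.15). The ato transcript itself did not pass (-0.06 ± 0.11, adjusted p = 0.87, with arrays at 0.04, 0.03 and -0.26). The EGFR list fell, with 8 of 17 genes lower and 9 adjusted over the list alone (adjusted p = 3.1e-08, and adjusted p = 0.048 with an estimated correlation). Of 15 Notch targets 9 fell and 1 rose, or 10 and 1 adjusted over the list alone (adjusted p = 3.6e-08, and adjusted p = 0.082 with an estimated correlation). Of 29 photoreceptor genes 6 fell and 2 rose, or 7 and 2 (adjusted p = 0.0042, and adjusted p = 0.23 with an estimated correlation). Ribosomal protein genes rose, 15 of 90 and 21 adjusted over the list alone (adjusted p = 5.2e-07, and adjusted p = 0.67 with an estimated correlation). Antimicrobial peptide genes were higher as a set with no member of 15 past the threshold (adjusted p = 0.025, and adjusted p = 0.46 with an estimated correlation). In limma 1681 probes changed, 666 higher and 1015 lower (574 against the mean of the other conditions). The number was 811 without replicate 3, in which the median of the muscle list was 0.58. Scanning day as a fixed block gave 3229, 1522 of them shared.

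In hh1 discs the hh transcript fell by 1.16 ± 0.17 (n = 4 arrays, adjusted p = 0.00021), with arrays at -0.84, -0.99, -1.68 and -1.03. This fall was not particular to hh1: hh was also lower in roDom homozygotes and did not pass between extra-R8 and stop-furrow discs. E(spl)m2-BFM (-1.27 ± 0.15), E(spl)mdelta-HLH (-1.26 ± 0.17), the EGFR inhibitor gene aos (-0.93 ± 0.14) and the cell cycle gene stg (-1.22 ± 0.20) fell. Vajk2 (4.17 ± 0.35, another probe at 1.37), Vajk3 (2.94 ± 0.19) and Obp99a (2.42 ± 0.41) rose. Lower were l(1)G0289 (-2.61 ± 0.20), pst (-1.97 ± 0.13) and the metalloprotease gene mmd (-1.89 ± 0.29, other probes from -0.15 to 0.09). The EGFR list fell with 7 of 17 genes lower, or 8 adjusted over the list alone (adjusted p = 0.00016, and adjusted p = 0.17 with an estimated correlation). The furrow list fell with 2 of 17, stg and hh, or 8 lower and 1 higher adjusted over the list alone (adjusted p = 0.00098, and adjusted p = 0.17 with an estimated correlation). Of 15 Notch targets 4 fell and E(spl)mbeta-HLH rose (0.97 ± 0.16), or 4 and 1 adjusted over the list alone (adjusted p = 0.0055, and adjusted p = 0.46 with an estimated correlation). Photoreceptor genes (lz of 29 lower, -1.26 ± 0.21) and mitosis genes (stg of 24 lower) fell as sets, with 1 gene each adjusted over the list alone (adjusted p = 0.028 and 0.041, and adjusted p = 0.40 and 0.90 with an estimated correlation). Ribosomal genes rose, 6 of 90 with 1 lower, or 10 and 1 adjusted over the list alone (adjusted p = 0.0050, and adjusted p = 0.90 with an estimated correlation). The Hedgehog pathway list, where hh was the 1 gene of 10 past the threshold, did not pass (adjusted p = 0.59). In limma 884 probes changed, 454 higher and 430 lower (320 against the mean of the other conditions). The number was 425 without replicate 4 and 521 without replicate 2. Blocking scanning day as fixed kept 279 of the 884, gave 286 higher and 461 lower, and under it Obp99a (2.88 ± 0.84), lz (-1.37) and stg (-1.06) lost their calls. A random block kept these 3.

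In roDom homozygotes, whose dominant rough allele halts the furrow, E(spl)mgamma-HLH fell by 2.30 ± 0.25 (n = 3 arrays, adjusted p = 2.1e-05). Nrt (-2.0 ± 0.26, other probes from -0.36 to 0.05) and the insulin-like gene Ilp2 (-2.41 ± 0.39, arrays from -4.35 to -0.19) fell too. The tektin gene Tektin-C rose by 2.72 ± 0.16 (adjusted p = 5.6e-09), Arpc1 by 1.85 ± 0.28 and the muscle gene Mp20 by 2.0 ± 0.56 (arrays from 0.18 to 3.57). The rough transcript ro did not pass (0.13 ± 0.13, adjusted p = 0.60, with arrays at 0.06, -0.04 and 0.40). The EGFR list fell with 5 of 17 genes lower, aos (-1.09 ± 0.16) among them, or 9 adjusted over the list alone (adjusted p = 8.4e-08, and adjusted p = 0.067 with an estimated correlation). Of 29 photoreceptor genes phyl (-1.62 ± 0.34), sev (-1.52 ± 0.23), scrt (-1.06 ± 0.26) and lz (-0.95 ± 0.24) fell. The list passed with these 4 genes, or 5 adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.23 with an estimated correlation). Furrow genes (3 of 17: hh, stg and ato) and Notch targets (2 of 15: E(spl)mgamma-HLH and E(spl)mdelta-HLH) fell too, or 5 and 3 adjusted over the list alone (adjusted p = 0.011 and 0.0064, and adjusted p = 0.23 and 0.35 with an estimated correlation). The hemocyte list fell with lz the 1 gene of 10 past the threshold and 7 adjusted over the list alone (adjusted p = 0.00075, and adjusted p = 0.20 with an estimated correlation). The mitosis list fell with stg of 24, also 1 adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.50 with an estimated correlation). Ribosomal genes rose, 15 of 90, or 38 adjusted over the list alone (adjusted p = 2e-17, and adjusted p = 0.23 with an estimated correlation). So did muscle genes, Act57B (1.52 ± 0.43) and Tm2 (0.72 ± 0.19) of 15, or 7 adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.39 with an estimated correlation).

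In limma 687 probes changed in roDom homozygotes, 242 higher and 445 lower, 95 of them at least 2-fold (78 against the mean of the other conditions). This number was 145 without replicate 1 and 251 without replicate 2. Mp20 lost its call without replicate 1 (1.35, adjusted p = 0.42) or 3 (1.88, adjusted p = 0.14). Act57B lost its call without any 1 of the 3 arrays (1.07, 1.86 and 1.57) and Tm2 without replicate 1 (0.22). Among the lower genes, lz and stg lost theirs without any 1 array (lz -1.18, -1.01 and -0.70; stg -1.12, -1.05 and -0.87). So did phyl (-1.74 and -1.55), scrt (-0.91 and -1.04) and ato (-0.59 and -0.48) without replicate 1 or 2, and hh (-0.93) without replicate 1. Replicates 1 and 2 were each alone on their scanning day, so under a fixed day block only replicate 3 shared a day with other groups. That block therefore compares this group with the others through replicate 3 alone, and it left 113 probes, 42 of them shared. Under it Tektin-C (2.25 ± 0.36), E(spl)mdelta-HLH (-1.42) and phyl (-1.61) kept their calls. Those of E(spl)mgamma-HLH (-1.91 ± 0.43, adjusted p = 0.070) and Nrt (-1.85 ± 0.39, adjusted p = 0.054) were lost with little change in size, while Arpc1 (0.89 ± 0.55), Mp20 (0.19 ± 0.71) and Ilp2 (-0.34 ± 0.16) shrank and Act57B turned to -0.44. The fixed block also ended the calls of sev (-1.21), aos (-1.07), scrt (-1.08), lz (-1.17), hh (-0.91), stg (-1.42), ato (-0.18) and Tm2 (0.01). Of these 17 genes a random block ended the calls of Mp20 (1.82), Act57B (1.33) and Tm2 (0.65). The deposited values, where 2 arrays of this group could be used, gave 14 probes higher and 61 lower.

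In roDom heterozygotes ro rose by 1.04 ± 0.15 (n = 2 arrays, adjusted p = 0.00095), with arrays at 0.91 and 1.17. Tektin-C (2.07 ± 0.20, adjusted p = 2.7e-05), Vajk2 (2.0 ± 0.49, another probe at 0.24) and toy (1.99 ± 0.47) rose. The peptidase gene SP1029 (-2.79 ± 0.69), the nuclear receptor gene Hr39 (-2.31 ± 0.43) and bnb (-2.28 ± 0.35) fell. The EGFR list fell, 7 of 17, or 10 lower and 1 higher adjusted over the list alone (adjusted p = 7.4e-07, and adjusted p = 0.11 with an estimated correlation). Notch targets fell, E(spl)mdelta-HLH (-1.41 ± 0.24) and E(spl)m3-HLH (-1.03 ± 0.23) of 15, or 7 lower and 1 higher (adjusted p = 0.00020, and adjusted p = 0.20 with an estimated correlation). Photoreceptor genes fell, 4 of 29 with chp (-2.16 ± 0.34), ttk (-1.42 ± 0.36, other probes from -0.56 to 0.01), sev and lz, also 4 adjusted over the list alone (adjusted p = 0.0092, and adjusted p = 0.20 with an estimated correlation). Ecdysone genes fell, 4 of 15 with 1 higher, or 6 and 2 (adjusted p = 0.011, and adjusted p = 0.29 with an estimated correlation). Ribosomal genes rose, 30 of 90, or 51 adjusted over the list alone (adjusted p = 3.3e-25, and adjusted p = 0.18 with an estimated correlation). DNA replication genes rose, E2f1 of 26 (0.69 ± 0.13), or 3 (adjusted p = 0.0092, and adjusted p = 0.53 with an estimated correlation). Phototransduction genes rose, 3 of 18 and 3 adjusted over the list alone (adjusted p = 0.019, and adjusted p = 0.20 with an estimated correlation). The rhodopsin gene Rh6 was detected on 1 of the 2 arrays, which stood at 0.17 and 3.30, so no fold is given for the group. The arrestin gene Arr1 was higher by 1.40 ± 0.21 and the channel gene trpl by 1.18 ± 0.23. The source name of replicate 2 gives no zygosity, and its title was used. In limma 809 probes changed, 292 higher and 517 lower (8 against the mean of the other conditions). The number was 10 without replicate 2 and 109 without replicate 1, where the remaining array is assumed to vary like the other groups. Without replicate 2 ro reached 0.87 (adjusted p = 0.18), chp -1.94 (0.18), E(spl)mdelta-HLH -1.22 (0.25), Rh6 0.18 (1), Arr1 0.51 (0.25) and trpl 0.17 (0.88). Without replicate 1 the last 3 reached 3.29, 2.29 and 2.18. Without either array Vajk2 (2.18 and 1.83), toy (2.04 and 1.94), SP1029 (-2.99 and -2.59), Hr39 (-2.38 and -2.24), bnb (-2.17 and -2.38) lost their calls. So did E(spl)m3-HLH (-1.29 and -0.76), ttk (-1.72 and -1.12), sev (-1.64 and -1.07), lz (-1.64 and -1.03) and E2f1 (0.65 and 0.72). Scanning day as a fixed block kept 174 of the 809, gave 279 higher and 213 lower, and ended the calls of Vajk2 (1.32 ± 0.62), SP1029 (-1.73 ± 0.65), Hr39 (-1.29 ± 0.44), E(spl)m3-HLH (-0.87), chp (-1.98), ttk (-0.81), sev (-0.79), lz (-1.20), Rh6, Arr1 (1.58) and trpl (1.20). A random block ended those of SP1029 (-2.62) and ttk (-1.35). The deposited values gave 464 higher and 480 lower. Between homozygotes and heterozygotes ro differed by -0.91 ± 0.20 (adjusted p = 0.34). Here limma called 1 probe, CG12914 (-0.92 ± 0.14, adjusted p = 0.027), which was chosen after its values were seen, with 1573 at an unadjusted p under 0.05. That number was 175 without homozygote replicate 3, 4 without either heterozygote array and 0 without homozygote replicate 1 or 2.

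In homozygotes of E(roDom)2033, an enhancer of roDom, E(spl)mgamma-HLH fell by 3.71 ± 0.25 (n = 3 arrays, adjusted p = 3.8e-09). The genes chp (-2.63 ± 0.28), lz (-2.58 ± 0.24) and ru (-2.73 ± 0.26) fell too. Vajk2 (4.27 ± 0.40, another probe at 1.76), Vajk3 (3.72 ± 0.22) and the neuroblast homeobox gene ind (2.96 ± 0.14, adjusted p = 3e-11) rose. The salivary glue genes Sgs7 (-3.63 ± 1.18, adjusted p = 0.047) and Sgs5 (-3.59 ± 0.91, adjusted p = 0.012, another probe at -1.84) were lower. Photoreceptor genes fell, 10 of 29, or 11 adjusted over the list alone. So did Notch targets, 8 of 15, or 11, and EGFR genes, 8 of 17, also 8 (adjusted p = 2.4e-06, 2e-08 and 2e-06, and adjusted p = 0.051 in each with an estimated correlation). Furrow genes fell, 5 of 17 with 1 higher, or 7 and 1 adjusted over the list alone (adjusted p = 0.026, and adjusted p = 0.24 with an estimated correlation). Ecdysone genes fell, 5 of 15, or 6, with br (-1.63 ± 0.25, other probes from -0.41 to -0.05) and Hr3 (-1.51 ± 0.26, another probe at -0.03) among them (adjusted p = 0.0023, and adjusted p = 0.24 with an estimated correlation). DNA replication genes rose, 15 of 26 with 1 lower, or 20 and 1 adjusted over the list alone (adjusted p = 9.5e-09, and adjusted p = 0.16 with an estimated correlation). Among them were RnrS (1.37 ± 0.17) and the primase gene Prim1 (1.14 ± 0.19). In limma 2167 probes changed, 1164 higher and 1003 lower (855 against the mean of the other conditions). The number was 571 without replicate 1 and 893 without replicate 3. Blocking scanning day as fixed kept 680 of the 2167, turned Sgs7 (0.99) and Sgs5 (0.26), and ended the call of Prim1 (0.73). A random block kept Prim1 (1.01) and ended the calls of Sgs7 (-2.84, adjusted p = 0.19) and Sgs5 (-2.92, adjusted p = 0.078). With array series as a block Sgs7 did not pass either (-3.60, adjusted p = 0.059). Sgs7 lost its call without any 1 array (-4.20, -3.68 and -3.11) and Sgs5 without replicate 1 (-4.04) or 3 (-3.26). With the labels' other reading, in which replicates 2 and 3 are heterozygous, 567 probes passed. Vajk2 stood at 4.78, 3.60 and 4.30 in replicates 1 to 3 and at -0.01 and -0.33 in the 2 arrays titled heterozygous. It was named for its rise under the titled grouping, so these values cannot settle which labels are right.

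In E(roDom)2033 heterozygotes ind rose by 4.44 ± 0.17 (n = 2 arrays, adjusted p = 5.2e-13), the immune-induced gene IM33 by 4.71 ± 0.46 (adjusted p = 7.5e-06) and the fat body gene Fbp2 by 4.63 ± 1.00 (adjusted p = 0.015). bnb (-2.13 ± 0.35), the receptor phosphatase gene Lar (-1.75 ± 0.35) and neur, a ligase for Notch ligands (-1.61 ± 0.29), fell. EGFR genes fell, aop (-1.33 ± 0.35), aos (-1.03 ± 0.20) and S (-0.43 ± 0.11) of 17, or 6 adjusted over the list alone (adjusted p = 0.00032, and adjusted p = 0.42 with an estimated correlation). Photoreceptor genes fell with B-H2 of 29 (-0.72 ± 0.18, another probe at -0.33), or 4 (adjusted p = 0.031, and adjusted p = 0.45 with an estimated correlation). Notch targets fell with Tom (-1.11 ± 0.21) and E(spl)mdelta-HLH (-0.95 ± 0.24) of 15 lower and E(spl)mbeta-HLH higher (1.13 ± 0.22), or 2 and 1 adjusted over the list alone (adjusted p = 0.045, and adjusted p = 0.71 with an estimated correlation). Fat body genes rose, Fbp2 of 11, or 2 adjusted over the list alone (adjusted p = 0.045, and adjusted p = 0.71 with an estimated correlation). Ribosomal genes rose, RpL35 (0.76 ± 0.20) and RpS21 (0.66 ± 0.16) of 90, also 2 (adjusted p = 0.0096, and adjusted p = 0.74 with an estimated correlation). In limma 568 probes changed, 256 higher and 312 lower (29 against the mean of the other conditions). That number was 21 without replicate 1 (17 higher, 4 lower) and 62 without replicate 2 (56 higher, 6 lower), so the balance of the 2 directions did not hold. Replicate 1 was 1 of the 3 arrays with raised muscle genes (list median 0.38). Without these 3 arrays 103 probes passed, and Fbp2 (4.21), bnb (-2.02) and Lar (-2.07) lost their calls. Every gene named here except ind and IM33 lost its call without replicate 1 and without replicate 2. The values were 3.85 and 5.41 for Fbp2, -2.0 and -2.25 for bnb, -1.96 and -1.54 for Lar, and -2.02 and -1.21 for neur. They were -1.84 and -0.81 for aop, -1.31 and -0.75 for aos, -0.49 and -0.37 for S, and -0.75 and -0.69 for B-H2. They were -1.15 and -1.07 for Tom, -0.76 and -1.14 for E(spl)mdelta-HLH, 1.34 and 0.92 for E(spl)mbeta-HLH, 0.75 and 0.77 for RpL35, and 0.58 and 0.73 for RpS21. A fixed block for scanning day kept 208 of the 568, gave 395 higher and 206 lower, and ended the calls of Fbp2 (2.84 ± 1.06), aop (-0.54), aos (-0.78), S (-0.32), Tom (-0.81) and RpL35 (0.53). Its random form, with 179 higher and 145 lower, ended those of aop (-1.15), S (-0.38) and RpL35 (0.67). The deposited values, with 1 usable array, gave 17 higher and 3 lower.

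Homozygotes minus heterozygotes of E(roDom)2033 ask what the second mutant copy adds. No scanning day held arrays of both groups, so an effect of the second copy cannot be told apart from one of the day by direct comparison. Vajk2 (4.44 ± 0.64, n = 3 against 2 arrays, adjusted p = 0.0010, another probe at 1.64), Vajk3 (3.60 ± 0.34) and the glutathione transferase gene GstE6 (2.03 ± 0.22) were higher in homozygotes. IM33 (-4.49 ± 0.60), the glue gene ng3 (-3.56 ± 0.42) and E(spl)mgamma-HLH (-3.08 ± 0.39) were lower. The mean of a list of salivary gland markers was 1.21 and 0.34 in heterozygote arrays and -1.54 to -1.09 in homozygotes. Carry-over of salivary gland cells thus stays open for ng3. In limma 170 probes differed, 77 higher and 93 lower. That number was 15 without heterozygote replicate 1, 81 without heterozygote replicate 2 (15 higher, 66 lower), 51 without homozygote replicate 1 and 70 without homozygote replicate 3. IM33 lost its call without heterozygote replicate 1 (-3.66, adjusted p = 0.061). Scanning day as a fixed block left 278, 29 of them shared, and ended the calls of IM33 (-2.40 ± 0.74) and ng3 (-1.47 ± 0.65), which a random block kept. The labels' other reading left 20 (19 higher, 1 lower), and the deposited values gave 10 higher and 36 lower.

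In roX63 discs, mutant for rough, the muscle genes Mhc (3.63 ± 0.61, n = 3 arrays, adjusted p = 0.00058) and Mlc2 (2.89 ± 0.57) rose, as did Fbp2 (3.36 ± 0.82) and Tektin-C (3.15 ± 0.16). The glue genes Sgs7 (-4.11 ± 1.18, adjusted p = 0.025), Sgs5 (-3.95 ± 0.91) and Sgs8 (-3.59 ± 0.98, another probe at -2.23) were lower. Another probe of Sgs5 stood at -1.01 and did not pass (adjusted p = 0.24). The ro transcript did not pass (-0.08 ± 0.13, adjusted p = 0.84, with arrays at 0.16, -0.24 and -0.17). EGFR genes fell, 8 of 17, or 9 adjusted over the list alone (adjusted p = 0.00045, and adjusted p = 0.21 with an estimated correlation). Ecdysone genes fell, 5 of 15 with ImpE2 (-3.47 ± 0.68) the lowest, or 8 lower and 1 higher (adjusted p = 0.014, and adjusted p = 0.35 with an estimated correlation). Glial genes fell with bnb (-2.49 ± 0.29) and nrv2 (-1.23 ± 0.21, another probe at -0.01) of 11, or 3 (adjusted p = 0.030, and adjusted p = 0.21 with an estimated correlation). Muscle genes rose, 5 of 15, or 6 adjusted over the list alone (adjusted p = 0.0045, and adjusted p = 0.35 with an estimated correlation). The median of this list was 0.69 in replicate 2. Ribosomal genes rose, 22 of 90 with 1 lower, or 32 and 1 (adjusted p = 1e-09, and adjusted p = 0.35 with an estimated correlation). DNA replication genes rose, 5 of 26 with 1 lower, or 6 and 1, Orc2 (0.91 ± 0.16) among them (adjusted p = 0.040, and adjusted p = 0.56 with an estimated correlation). In limma 2101 probes changed, 941 higher and 1160 lower (421 against the mean of the other conditions), and 625 without replicate 3. Fbp2 lost its call without replicate 2 (2.24, adjusted p = 0.15) or 3 (3.30, adjusted p = 0.095). Sgs7 (-3.66, -4.36 and -4.35) and Sgs8 (-3.35, -3.59 and -3.86) lost theirs without any 1 array. Blocking scanning day as fixed kept 399 of the 2101, and ended the calls of Mhc (2.34 ± 0.67), Mlc2 (1.73), Fbp2 (1.97 ± 0.98), ImpE2 (-2.82) and nrv2 (-0.79), which a random block kept. With the fixed block Sgs7 reached -7.47, Sgs5 -6.79 and Sgs8 -6.30, and with the random block -4.62, -4.41 and -4.01.

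In Su(roDom)519 discs, mutant for a suppressor of roDom, the kinase gene Pka-C3 (1.55 ± 0.25, n = 3 arrays, adjusted p = 0.0015), toy (1.49 ± 0.39) and the membrane contact gene Vap33 (1.42 ± 0.32) rose. Sgs7 (-5.00 ± 1.18, adjusted p = 0.019), Sgs8 (-4.11 ± 0.98, another probe at -3.07) and Sgs5 (-3.84 ± 0.91) were lower. Another probe of Sgs5 stood at -1.75 and did not pass (adjusted p = 0.056). EGFR genes fell as a set with Sos (-0.39 ± 0.09) the 1 gene of 17 past the threshold and 6 adjusted over the list alone (adjusted p = 0.00048, and adjusted p = 0.19 with an estimated correlation). Glial genes fell with bnb (-1.75 ± 0.29) and nrv2 (-0.80 ± 0.21, another probe at 0.05) of 11, also 2 (adjusted p = 0.0046, and adjusted p = 0.058 with an estimated correlation). DNA replication genes rose with PCNA of 26 (0.78 ± 0.20), or 5 adjusted over the list alone (adjusted p = 0.00048, and adjusted p = 0.66 with an estimated correlation). Ribosomal genes rose, 5 of 90 with 1 lower, or 6 and 1 (adjusted p = 0.0022, and adjusted p = 0.66 with an estimated correlation). In limma 722 probes changed, 390 higher and 332 lower (75 against the mean of the other conditions). That number was 78 without replicate 2, 193 without replicate 1 and 211 without replicate 3. Leaving out any 1 array ended the calls of Sgs7 (-5.16, -5.22 and -4.65), Sgs8 (-4.17, -4.05 and -4.14) and Sgs5 (-3.89, -3.47 and -4.17). It also ended those of toy (1.72, 1.51 and 1.27), Vap33 (1.52, 1.55 and 1.21), Sos (-0.35, -0.41 and -0.39), PCNA (0.82, 0.59 and 0.94) and nrv2 (-0.85, -0.79 and -0.76). A fixed block for scanning day kept 128 of the 722. It ended the calls of Pka-C3 (1.54 ± 0.37, adjusted p = 0.054) and toy (1.39 ± 0.34, adjusted p = 0.055) with little change in size, and those of Vap33 (1.09 ± 0.28), Sos (-0.27), PCNA (0.70) and nrv2 (-0.36). Of these 6, Pka-C3 (1.62) and Vap33 (1.29) kept their calls with a random block. With the fixed block Sgs7 reached -8.36, Sgs8 -6.83 and Sgs5 -6.69, and with the random block -5.51, -4.54 and -4.31.

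**Figure D3:**
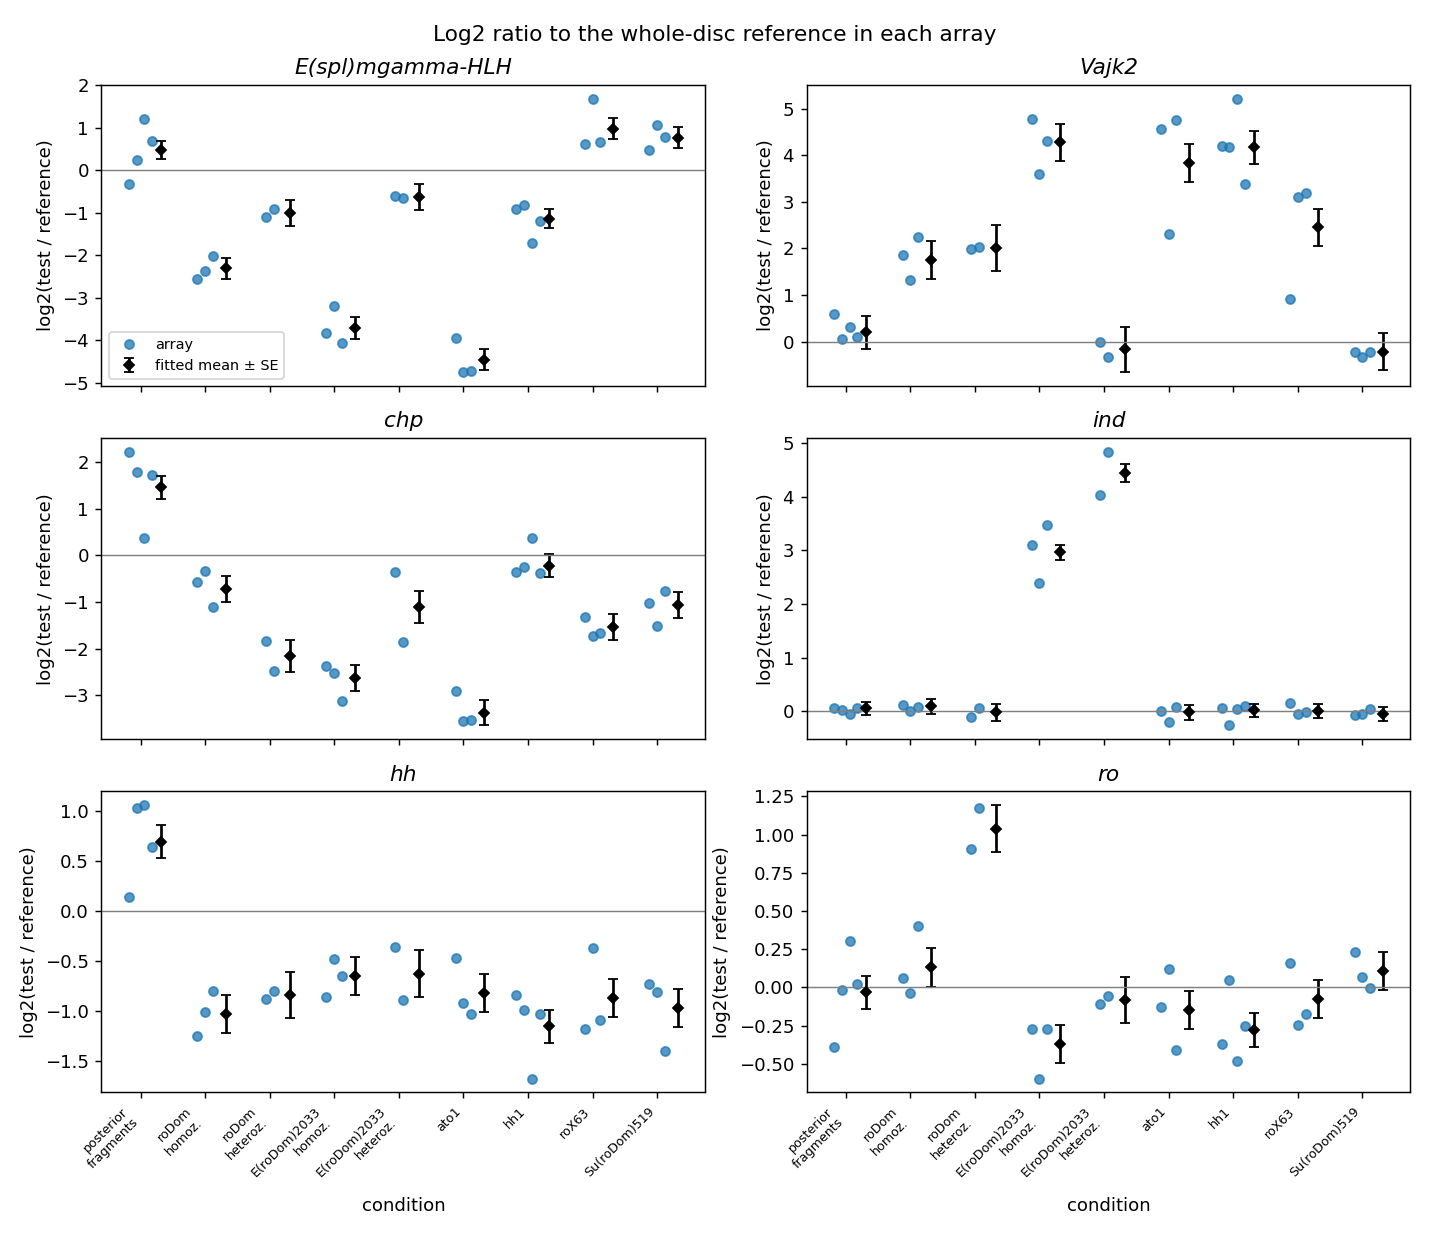
Log2 ratio over the reference (vertical axis) of E(spl)mgamma-HLH, Vajk2, chp, ind, hh and ro in the 9 conditions, with 1 panel per gene. Points are arrays and markers with bars are the fitted mean and its standard error, with ind at 2.96 in E(roDom)2033 homozygotes and 4.44 in heterozygotes.

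Sex-linked dosage and antennal disc lists passed camera in none of the 9 conditions or 2 group differences. With fry the sex-linked list passed in roX63 discs (adjusted p = 0.014, and adjusted p = 0.14 with camera). In roDom homozygotes, for example, the antennal list (adjusted p = 0.23) held al (1.02 ± 0.24) and Lim1 (1.01 ± 0.24, other probes from -0.17 to -0.10) higher and danr (-1.20 ± 0.27) lower, and each lost its call without replicate 1 (0.73, 0.89 and -1.16) or 2 (0.67, 0.61 and -1.05). In roX63 discs 3 of 15 antimicrobial peptide genes were higher, DptB (1.72 ± 0.40), Mtk (1.47 ± 0.25) and DptA (0.95 ± 0.23), with the list not past the threshold (adjusted p = 0.14). Without replicate 2 DptB reached 0.56, Mtk 0.80 and DptA 0.38 (adjusted p = 0.20). Without replicate 1 DptB reached 2.61 and DptA 1.45. DptA also lost its call without replicate 3 (1.02, adjusted p = 0.061).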

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

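The tests of ind by scanning day and by dye, both tests of the glue genes and the differences between 2 mutant groups were chosen only after the result was seen; the test of the neighbours of ind and the splits of the arrays were chosen before.

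The gene ind was high in all 5 arrays of both E(roDom)2033 groups (2.39 to 4.84) and at most 0.15 in the 22 other arrays. A shared effect of the scanning day is argued against by the 14 arrays of other genotypes scanned on the same days, whose median was 0.0111 (from -0.27 to 0.15). Dye is argued against by the means of the E(roDom)2033 arrays, 3.57 with the test RNA in Cy3 and 3.57 in Cy5. Extra copies of the region are argued against by the 20 nearest measured genes, whose median was 0.0831 over both groups and which reached at most 0.41 in homozygotes. In heterozygotes CG12310 (2.92), CG13460 (2.28), CG18649 (1.94) and CG13461 (1.39) on 1 side of ind were higher, all but CG12310 past the threshold, and so were CG5114 (0.56) and Rpn12R (0.43) on the other side, so a local change there stays open, as does the hypothesis that the E(roDom)2033 chromosome or a shared background may raise ind.

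The salivary glue genes lay far from 0 with different signs between arrays: the mean of 10 such genes, taken from a list of salivary gland markers, ran from -1.75 to 1.32. It was below -1 in 14 arrays and above 1 in 3: roDom heterozygote replicate 2 (1.03), E(roDom)2033 heterozygote replicate 1 (1.21) and ato1 replicate 3 (1.32). Varying carry-over of salivary gland cells, in the reference or the test RNA, cannot be told apart from other sources, because the median correlation over 45 pairs of these genes was 0.268, with the lowest pair at -0.149. Genotype stays open as well: 0.499 of the spread lay between groups (0.395 to 0.621 without 1 array, 0.286 as the median with shuffled labels), against 0.251 between scanning days, and the widest range within a group was 2.92. The mutated genes could act on glue genes by way of larval age, which was not recorded and was not tested.

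Of 100 splits of the 19 arrays of extra-R8 and stop-furrow discs, 1, the real one, gave as many changed probes as the real split. It gave 811 in a fit without genotype means, and the highest other 784. These splits break up genotypes and scanning days, within which arrays resemble each other, so they cannot exclude chance for either. The split with 784 put 4 of the 5 arrays of 1 scanning day into the group of 6. They are 2 arrays each of E(roDom)2033 homozygotes and hh1, so scanning day and genotype as the structure behind this split cannot be told apart, and with scanning day as a fixed block the comparison left 357 probes. For posterior fragments and stop-furrow discs 2 of 100 splits, the real one included, were as large (real 928, highest other 1088). Another split thus gave more than the real one, and chance is not excluded for genotypes or days here either. The split with 1088 took its 4 arrays from that same scanning day, and 3 of the 4 fragments also share a day, so a grouping by day is not excluded, and the blocked number was 538. Splitting the 6 genotypes into 2 and 4 gave 1239 for the real split and 2020 for the highest other (E(roDom)2033 homozygotes and hh1), with 2 of 15 as large, and 15 splits are too few for a share under 0.05.

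Among 73 sets of 4 arrays, 6 held an array far from the other 3, where chance gives about 1 in 20. In posterior fragments lab was -2.55 in replicate 4 and -1.58 to -1.53 in the others. The median of the Notch target list was 0.28 in replicate 3 and -0.32 to -0.25 in the others. The median of the DNA replication list was -0.44 in replicate 1 and -0.04 to 0.00 in the others. The percent of probes detected was 47.2 in replicate 1 and 89.2 to 91.6 in the others. In hh1 the median of the fat body list was 0.33 in replicate 3 and -0.08 to -0.03 in the others. The median net reference signal was 65 intensity units in hh1 replicate 1 and 165 or more in the others.

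Mutant groups of the same class differed from each other in limma. Between roX63 and Su(roDom)519, 102 probes differed, with Tektin-C (3.18 ± 0.23), Cyp6t3 (2.66 ± 0.19), Ir76a (-2.44 ± 0.24) and Cyp9c1 (-2.23 ± 0.24) among them. Between ato1 and hh1, 515 probes differed: Hrb87F (-4.42 ± 0.21), E(spl)mgamma-HLH (-3.33 ± 0.33), chp (-3.15 ± 0.37) and ru (-2.95 ± 0.35) were lower in ato1 and Hsc70-2 (2.60 ± 0.20) higher. The change from heterozygotes to homozygotes differed between E(roDom)2033 and roDom for 8 probes, among them Vajk3 (3.62 ± 0.48), retn (-2.44 ± 0.34), Xport-A (-1.71 ± 0.25) and Lfg (-2.76 ± 0.44).

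Of the control spots that no comparison used, 3 kinds gave a median signal above the 95th percentile of empty spots, 13 intensity units. The median net test signal was 269 at CD2 spots (above it on 27 of 27 arrays), 41 at AE002620 spots (24 arrays) and 14 at Adeno spots (19 arrays). In the reference channel these spots gave 292, 43 and 12. GFP spots, at 8.5, were not above it (10 arrays were).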

How the results depend on the processing

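The alternatives with scanning day as a block, without arrays with raised muscle genes and against the mean of the other conditions were chosen only after the result was seen; the others were planned. Over all alternatives, 159 of 265 counts stayed within 1.5 times and 106 moved, 33 of 38 values of the posterior-enriched sets kept their direction and side of the threshold, 3 were weaker and 2 reversed. Of 4493 values for gene lists 4202 were the same, 189 weaker and 102 stronger, and of 9729 for named genes 8077 were the same, 1603 weaker, 37 stronger and 12 reversed. Where no reason is given below, the cause was not tested.

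Counts are of changed probes. With scale normalization between arrays there were 1432 in posterior fragments, 1287 in E(roDom)2033 homozygotes and 70 between E(roDom)2033 homozygotes and heterozygotes. A fit on the groups compared, which has fewer arrays, gave 117 in posterior fragments, 0 in roDom homozygotes, 83 in E(roDom)2033 homozygotes, 285 in ato1, 23 in hh1, 3696 in roX63, 1159 in Su(roDom)519, 0 between the roDom groups and 13 between the E(roDom)2033 groups. It could not be made for the heterozygotes of roDom or E(roDom)2033, since 2 arrays with a dye term leave no residual degrees of freedom. Without the dye term there were 410 in roDom homozygotes, 491 in roDom heterozygotes, 252 in E(roDom)2033 heterozygotes and 103 between the E(roDom)2033 groups. With a 2-fold limit the 13 comparisons gave, by construction fewer, 131 (posterior fragments), 95 and 223 (roDom homozygotes and heterozygotes), 315 and 132 (E(roDom)2033 homozygotes and heterozygotes), 330 (ato1), 92 (hh1), 342 (roX63), 81 (Su(roDom)519), 98 (extra-R8 minus stop-furrow), 308 (posterior minus stop-furrow), 0 (between the roDom groups) and 93 (between the E(roDom)2033 groups). With array series as a fixed block there were 202 in roDom homozygotes and 0 between the roDom groups. The 7th series alone gave 80 in roDom homozygotes, 768 for extra-R8 minus stop-furrow and 0 between the roDom groups, and in roDom homozygotes al (-0.21) and Lim1 (-0.0224) reversed. Print-tip loess, the filter on dim probes and leaving out every spot with a negative score each gave 0 between the roDom groups, where the comparison had 1.

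From the values the submitters deposited, 3 columns were left out, because that of hh1 replicate 2 is the negative of that of Su(roDom)519 replicate 3 and those of roDom homozygote replicate 1 and E(roDom)2033 heterozygote replicate 2 had lost zeros. The remaining ones gave 75 in roDom homozygotes, 20 in E(roDom)2033 heterozygotes (1 array), 404 in hh1, 817 for extra-R8 minus stop-furrow, 0 between the roDom groups and 46 between the E(roDom)2033 groups, and the set lower in posterior fragments had a median of -0.00106 in extra-R8 minus stop-furrow discs, which did not pass. That set had -0.0137 without roX63 and -0.0361 without roDom homozygotes, and neither passed. Reading the conflicting labels as heterozygous gave 567 in E(roDom)2033 homozygotes (1 array), 1221 in heterozygotes and 20 between them. Without the 3 arrays with raised muscle genes there were 103 in E(roDom)2033 heterozygotes, 697 in ato1, 0 between the roDom groups and 28 between the E(roDom)2033 groups. Against the mean of the other conditions there were 1420 in posterior fragments, 78 and 8 in roDom homozygotes and heterozygotes, 855 and 29 in E(roDom)2033 homozygotes and heterozygotes, 574 in ato1, 320 in hh1, 421 in roX63 and 75 in Su(roDom)519.

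With scanning day as a fixed block there were 474 in posterior fragments, 113 and 492 in roDom homozygotes and heterozygotes, 1239 in E(roDom)2033 homozygotes, 3229 in ato1, 656 in roX63, 373 in Su(roDom)519, 357 for extra-R8 minus stop-furrow, 538 for posterior minus stop-furrow and 278 between the E(roDom)2033 groups. The posterior-enriched sets reversed to -0.28 (higher) and 0.22 (lower). These sets were called anew, and under this block the correlation of the estimates that the design builds in was -0.234, against -0.045 without it. Reversed too were Sgs7 (0.99) and Sgs5 (0.26) in E(roDom)2033 homozygotes, RpL10 in posterior fragments (0.28) and posterior minus stop-furrow (0.25), al (-0.16) and Act57B (-0.44) in roDom homozygotes, ihog (0.14) and Hsp27 (0.0926) in extra-R8 minus stop-furrow, and puc (-0.0198) and MsrA (0.0684) in posterior minus stop-furrow. As a random block, scanning day gave 379 in posterior fragments, 408 in roDom heterozygotes, 324 in E(roDom)2033 heterozygotes, 1259 in roX63, 290 in Su(roDom)519, 472 for extra-R8 minus stop-furrow, 891 for posterior minus stop-furrow, 0 between the roDom groups and 86 between the E(roDom)2033 groups. The counts of 0 are from limma, with 1573 probes between the roDom groups and 3426 in roDom homozygotes at an unadjusted p under 0.05 in the fit reported.

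Leaving out 1 array at a time, the counts ran from 279 to 529 in posterior fragments, 145 to 632 in roDom homozygotes, 10 to 109 in roDom heterozygotes, 571 to 2187 in E(roDom)2033 homozygotes, 21 to 62 in E(roDom)2033 heterozygotes, 811 to 1577 in ato1, 425 to 1091 in hh1, 625 to 1460 in roX63, 78 to 211 in Su(roDom)519, 734 to 1815 for extra-R8 minus stop-furrow, 788 to 1464 for posterior minus stop-furrow, 0 to 175 between the roDom groups and 15 to 188 between the E(roDom)2033 groups. The lowest values came without posterior replicate 4, roDom homozygote replicate 1, roDom heterozygote replicate 2, E(roDom)2033 homozygote replicate 1 and heterozygote replicate 1, ato1 replicate 3, hh1 replicate 4, roX63 replicate 3 and Su(roDom)519 replicate 2. A lone remaining array is assumed to vary like the other groups. No paired analysis was possible because replicate numbers follow the order of deposit and pair no arrays, while scanning day, which links some arrays across groups, was fitted as a block instead. Many gene lists that passed did not pass without some 1 array of their group. In roDom homozygotes these were the Notch (replicate 3), mitosis (2) and muscle (1) lists, in roDom heterozygotes photoreceptor, DNA replication and phototransduction (2). In E(roDom)2033 homozygotes it was the furrow list (1 or 2), in the heterozygotes photoreceptor, EGFR and ribosomal (2) and Notch and fat body (1). In ato1 they were photoreceptor (1), antimicrobial and ribosomal (3), in hh1 photoreceptor (1 or 3), Notch (3), mitosis (1, 3 or 4) and ribosomal (1 or 3). In roX63 they were DNA replication (1 or 2), glia and muscle (2), and in Su(roDom)519 ribosomal (2). In posterior minus stop-furrow the ribosomal list was also lost without ato1 replicate 3 or hh1 replicate 1. Signal over background limits the genes near the floor: 15250 probes passed the filter on dim probes.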

Other observations

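The contrast of the mutants' mean with the reference, the contrast of the E(roDom)2033 groups with the other conditions, the test of the extra round of amplification and the test of dye on probes called with 1 dye were chosen only after the result was seen, and a first test of dye was planned.

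Across the mean of the 8 mutant groups, limma called 5380 probes against the reference, 2670 higher and 2710 lower. Among the lowest were the brightest probes of Nrt (-1.70 ± 0.09, other probes from -0.24 to -0.17) and Ank2 (-1.63 ± 0.09, other probes from -0.11 to 0.11), chp (-1.60 ± 0.10) and neur, a ligase for Notch ligands (-1.49 ± 0.09). The glue genes Sgs7 (-2.64 ± 0.43), Sgs5 (-2.39 ± 0.34) and Sgs8 (-2.28 ± 0.36) and the ecdysone-induced ImpE2 (-1.73 ± 0.25) were lower too. Higher were Vajk2 (2.26 ± 0.15), Vajk3 (1.63 ± 0.08), the fat body genes Fbp2 (2.07 ± 0.30) and Lsp1gamma (1.30 ± 0.30), the odorant-binding Obp99b (1.88 ± 0.34), the muscle gene Mhc (1.48 ± 0.22) and Sps2, which serves selenoprotein synthesis (1.42 ± 0.05).

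Against the mean of the other 7 conditions, the E(roDom)2033 groups differed in 242 probes, 152 higher and 90 lower. Beside ind (3.69 ± 0.12), the mucin gene Muc68Ca (1.79 ± 0.33), IM33 (1.79 ± 0.33) and the glue genes ng3 (1.69 ± 0.23), ng1 (1.27 ± 0.28) and ng2 (1.26 ± 0.28) were higher in the mean of both groups. That of IM33 and the glue genes came from the heterozygotes: IM33 stood at 5.30 and 4.13 in their arrays and from -0.10 to 0.93 in homozygotes, ng3 at 4.70 and 3.09 against 0.20 to 0.49, and the mean of the salivary list at 1.21 and 0.34 against -1.54 to -1.09. The cathepsin gene CtsB (-1.79 ± 0.15), the glutathione transferase gene GstE1 (-1.55 ± 0.21) and Tektin-C (-1.16 ± 0.14) were lower, as were the eye gene eya (-1.01 ± 0.25) and scrt (-0.99 ± 0.23).

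The changes shared by the mutants were weighed against the extra round of amplification, which every test RNA had and the reference lacked, and which as the whole cause would give posterior fragments about the same size. In the fragments the 2670 higher probes had a median of 0.03 against 0.21 in the mutants, and the 2710 lower ones -0.04 against -0.25, so that the higher of the 2 ratios was 0.151, with single arrays at up to 0.315 and 0.390. The planned test of dye, in which 91.7% of the 5380 probes had the same sign in the arrays of both dyes, decides nothing, because these probes were called on the same arrays in a fit with a dye term. The later test of dye cannot decide it for these probes either. A fit without a dye term called 2163 probes on the 12 mutant arrays with the test RNA in Cy3. Of these, 76.2% had the same sign on the 11 Cy5 arrays. Of 6156 called on the Cy5 arrays, 66.7% had it on the Cy3 arrays. The share over all probes was 55.2%, and a bound of 75% was set for both directions. Calling on arrays of the same dye without a dye term also picks probes shifted by dye, so a shortfall on the other dye is built in. The 5380 probes were called in a fit with a dye term over arrays of both dyes. The mutants' tissue, whole discs of other genotypes and rearing, may account for the shared changes and was not tested.

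The dye term passed in limma for 3973 probes. Over all pairs of arrays the median correlation of log2 ratios across genes, which are not independent replicates, was 0.448 for the same group (29 pairs) and 0.186 for different groups (322 pairs). For different groups scanned on the same day it was 0.431 (40 pairs), and 0.163 on other days (282 pairs). Within the same group it was 0.502 on the same day (8 pairs) and 0.404 on other days (21 pairs). Arrays of different groups on 1 day thus agreed about as well as arrays of 1 group on other days.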
